A study of Mus musculus with 13 samples.

How the data were processed

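Total RNA of cultured mouse keratinocytes was labelled with biotin and hybridised to Affymetrix expression arrays, with 1 array for untreated cells and 1 array for each of 12 times after tamoxifen. Per the labels, all cultures carried a retroviral fusion of DNp63alpha with an estrogen receptor domain, RNA was extracted with Trizol, and biotinylated cRNA was made by the standard protocol of the array maker. The deposited values are intensities on a linear scale, 1 value per probe set and array, for 22690 probe sets. The software that summarised the probes and brought the arrays to a common level is not given in the sources used here. Array medians lay between 237.4 and 251.5 intensity units and upper quartiles between 642.7 and 660.3, so the arrays had been brought close to each other before deposit. Such scaling removes any change shared by most transcripts, and the changes given are relative to the bulk of the genes.

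The deposited intensities were used as log2(intensity + 16) with no further normalization. A fold on this scale understates the change of dim genes. Probe sets were named through the platform table, which gave 1 gene to 20393 probe sets, several genes to 691 and none to 1606. Those with several genes or none entered no test. Symbols of 20364 probe sets were updated through their Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Each of 12394 genes was represented by its probe set with the highest mean. Genes below the 40th percentile of mean level, a log2 level of 7.83, were left out, which left 7436 genes. The number of arrays limits the precision: the median residual SD of a gene about its fitted curve was 0.0862 on the log2 scale.

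All models were fitted with limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend, two-sided, and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. All adjusted p-values of genes come from these limma fits. Time in hours was fitted as a straight line over all 13 arrays. A natural cubic spline of time with 3 degrees of freedom was tested with a moderated F-test. In a fit with 4 levels, the late window (180 to 240 min, 4 arrays) was set against the early window (20 to 80 min, 4 arrays), and the early window against the untreated array. Neighbouring times stand in for replicates in this fit, so change inside a window counts as spread, and the lone untreated array is assumed to vary like the others. No source says whether the arrays came from separate cultures, so p-values measure only the spread between these arrays. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. The 33 lists cover epidermal, cell cycle, signalling, stress and metabolic genes and markers of other cell types, and 30 of them had at least 5 tested genes. Of their 686 symbols 613 were found on the array and 471 were tested.

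The design, the lists, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls per hour past the threshold, the 5 largest peaks and 5 largest dips inside the course past the spline threshold alone, the 5 largest changes in each direction for each window contrast, and up to 4 members of each list with the largest slope (largest difference for early against untreated). Peaks and dips were taken by the side on which the fitted curve bends from the line joining its ends, which is looser than the rule, since such a curve need not turn inside the course. A fixed set of p63, keratin, p53, immediate early, Notch and reference genes was added, and unnamed, RIKEN and predicted Gm transcripts were skipped. 1 gene of that set is not reported here.

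The steps were tested on simulated data with 100 genes changed at each size. For a log2 change of 0.5 the straight line recovered 86% of changed genes, the spline 39%, late against early 83% and early against untreated 71%. For a log2 change of 1 the shares were 98%, 86%, 95% and 96%. Between 4.2% and 6.7% of the calls were false. The simulated noise was independent between genes and arrays, with no step between 60 and 80 min and no shift shared by genes of an array. These shares therefore need not hold for the real arrays. The alternatives tried were other filters on dim genes, pseudocounts, normalizations, ways of joining probe sets, moderation settings, array weights, time scales, spline flexibility, a Gapdh covariate for RNA integrity, and each array left out in turn. Fits by part of the time course, fits with a step between 60 and 80 min as a block, and fits without the 200 and 220 min arrays were chosen after seeing the data. Cells without the fusion protein and a time course without tamoxifen were not analysed here. Change due to handling, elapsed time or tamoxifen acting other than through the fusion protein is therefore not separated from change due to induction.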

Results

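Gene expression was followed in primary mouse keratinocytes, the main cells of the epidermis, in which a fusion of the p63 isoform DNp63alpha with an estrogen receptor domain could be switched on by tamoxifen. DNp63alpha lacks the amino-terminal activation domain and is the main p63 isoform of basal epidermal cells. The data comprised 1 array of untreated cells and 12 arrays taken every 20 min from 20 to 240 min after tamoxifen. There was 1 array per time and no replicate, so each change was judged against the scatter of arrays about a trend or within a window of 4 neighbouring times. Levels are given as log2(intensity + 16). Spearman correlations between pairs of arrays across all 22690 probe sets lay between 0.983 and 0.997, and no pair of arrays was identical.

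The transcript of Trp63, the gene of the induced factor, was measured in every array to see how far its probe sets reported the construct. The probe set with the highest mean, 1418158_at, read between 1028 and 1140 intensity units in the 4 arrays up to 60 min and between 1200 and 1396 in the 9 later arrays. Its fitted rise was 1.20-fold over 4 h (0.26 ± 0.096 on the log2 scale, SE, 13 arrays; adjusted p = 0.0425 among the 7436 genes). Among all 20393 probe sets named to 1 gene, dim ones included, its adjusted p was 0.0606 and the call was lost. The probe set 1451876_a_at read 658.8 in untreated cells, 1974 at 100 min and 1173 at 240 min. Its slope had an adjusted p of 0.765 among those 20393 probe sets. The probe set 1452027_a_at read 205.9 in untreated cells, 368 at 100 min and 288.6 at 240 min (adjusted p = 0.46 among the same 20393). Tamoxifen acts on the fusion protein, so the transcript need not change on induction, and the source of each probe set's signal, endogenous or retroviral, was not resolved. The Trp63 call was lost when the array at 0, 20, 40, 60, 140, 160, 180 or 200 min was left out, with slopes from 0.051 to 0.082 per hour over all 13 omissions. With a step between 60 and 80 min as a block the slope was -0.033 per hour.

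The linear trend asked which genes rose or fell across the 4 h. The largest fall was that of Egr2 (1427683_at), an immediate early transcription factor, 4.38-fold (-2.13 ± 0.295 on the log2 scale, SE, 13 arrays; adjusted p = 0.000159). Dusp10, a phosphatase of stress-activated kinases, fell 4.18-fold, and Ptgs2, the inducible cyclooxygenase, fell 4.05-fold (adjusted p = 9.77e-05). Dusp1, another kinase phosphatase, fell 3.43-fold and the vasoactive peptide gene Edn1 fell 3.26-fold. Akap12 fell 3.18-fold, Rptn (repetin, a late epidermal protein) 3.05-fold, Cidea 2.96-fold, Malat1 2.96-fold and Adm 2.91-fold. Malat1 read 10.06 in untreated cells and 8.76 ± 0.371 at 20 to 80 min (SD over 4 arrays). It did not pass late against early (adjusted p = 0.0885), the spline (0.076) or the test of a step between 60 and 80 min (0.139), and its trend was lost without the 200 and 220 min arrays (0.0631). The largest rise was that of the neutrophil chemokine Cxcl5 (1419728_at), 3.24-fold (1.70 ± 0.367 on the log2 scale, SE, 13 arrays; adjusted p = 0.0023). It was followed by Ddit4l, an inhibitor of mTOR signalling, at 2.51-fold, the receptor gene Tnfrsf18 at 2.48-fold and Sostdc1, a secreted BMP and Wnt antagonist, at 2.42-fold. Dcxr rose 2.32-fold, Ces2g 2.24-fold, Ak1 2.24-fold, Psrc1 2.12-fold, Sncg 2.05-fold and Plek2 2.05-fold. These folds come from the ends of a straight line, which can exceed the change of a gene that steps. For Cxcl5 the mean from 80 min lay 1.46 above the mean up to 60 min, against 1.70 along the line (log2 scale). The slope of Cxcl5 had the opposite sign from 80 to 240 min (-0.022 per hour), up to 60 min (-0.039) and with a step between 60 and 80 min as a block (-0.023). Up to 60 min alone the slopes of Ddit4l, Tnfrsf18, Sostdc1, Dcxr, Ces2g, Ak1, Sncg, Edn1 and Cidea were also opposite in sign. None of these opposite slopes passed the threshold.

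In all, 2968 of 7436 genes had a trend past the threshold, 1656 upward and 1312 downward. Falls were the larger changes: 302 genes fell and 155 rose by more than 1.5-fold, and 71 fell and 14 rose by more than 2-fold. Of the 1850 genes past the spline test, 892 had their best single break between the 60 and 80 min arrays, among breaks at every position. Of the same 1850 genes, 50.1% were fitted more closely by that step than by a straight line. Over all 7436 genes that step, fitted in place of the line, called 3104, of which 1613 were higher and 1491 lower from 80 min. Cxcl5 read 7.85 at 60 min and 9.18 at 80 min, and Egr2 read 9.05 at 60 min, 8.26 at 80 min and 7.86 at 100 min. When a step was fitted beside the straight line, 971 genes had a step between 60 and 80 min (379 upward, 592 downward), against 1 gene or 0 for a break at each other position from 20 to 200 min. With that step as a block the slope of 1 gene, Cby1, passed the threshold (0.15 ± 0.0203 per hour, adjusted p = 0.0283). Step and time run together over these arrays, so this fit tells slope from step poorly, and a miss does not show the absence of a slope. The slope of Rptn was -0.37 per hour with the block (adjusted p = 0.0687) and -0.40 without it. That of Cxcl5 was -0.023 with the block (adjusted p = 0.83) and 0.42 without it. In the 9 arrays from 80 to 240 min alone, 5 genes had a trend: Cby1 rose, and Lpin2, Dusp16, Nucb2 and Rnf11 fell (adjusted p = 0.0102 for Lpin2). In the 4 arrays up to 60 min alone no gene did. Cby1, Lpin2, Dusp16, Nucb2 and Rnf11 were chosen after their values were seen.

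**Figure D1:**
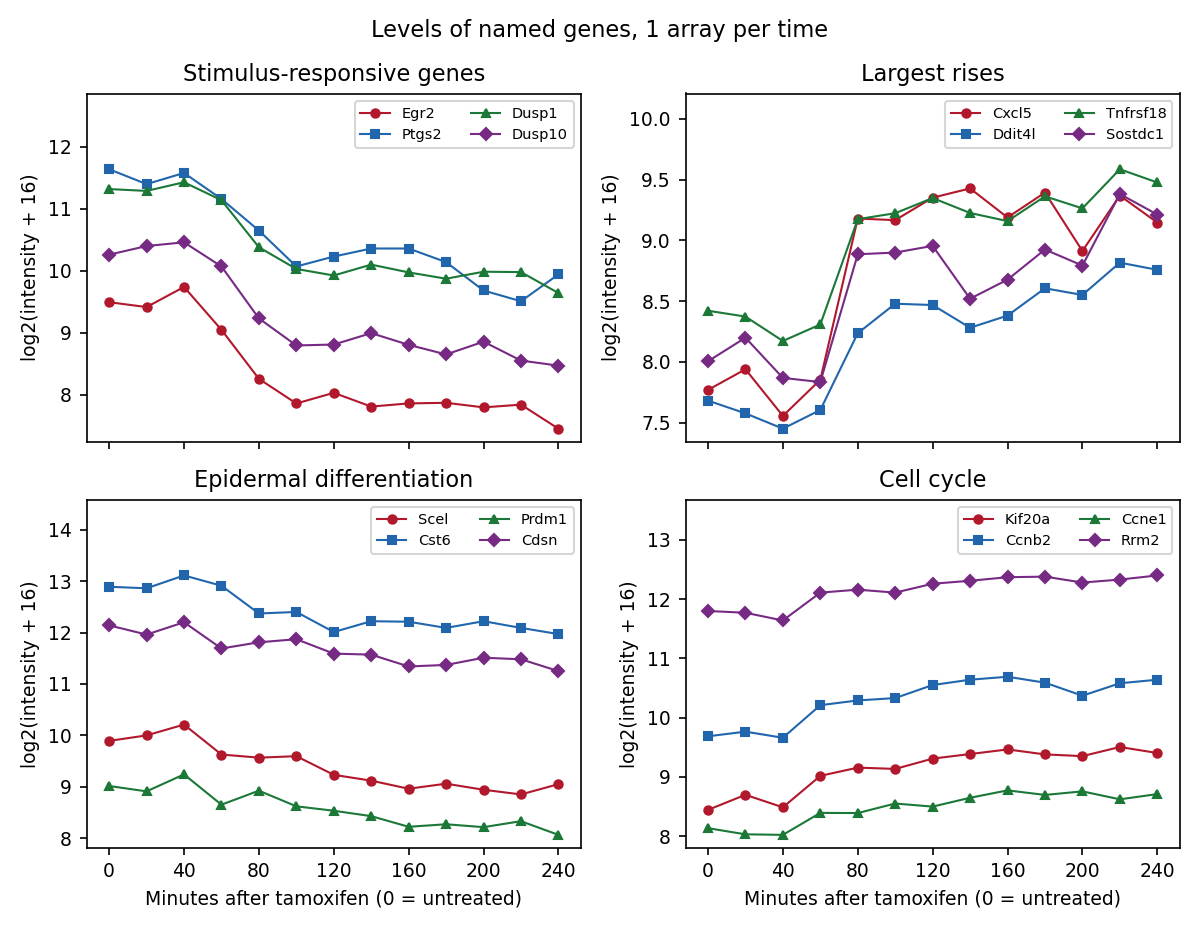
Level of named genes, as log2(intensity + 16), against minutes after tamoxifen, with 0 for untreated cells; each point is 1 array. Cxcl5 and Tnfrsf18 move to a higher level between 60 and 80 min (Cxcl5 from 7.85 to 9.18), and Scel reads 9.57 at 80 min and 9.05 at 240 min.

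Among the genes fixed in advance, the basal keratin Krt5 rose 1.08-fold (adjusted p = 0.00802), and its partner Krt14 did not pass the test (adjusted p = 0.872), nor did the suprabasal keratins Krt1 (0.768) and Krt10 (0.508). Krt14, at 14.15 in untreated cells, read near the top of the measured range, with Krt5 (13.89) below it, so a rise of either may be understated. The p53 targets Cdkn1a (adjusted p = 0.646) and Mdm2 (0.911) did not pass either. The AP-1 gene Jun fell 2.0-fold and Myc fell 1.45-fold, with adjusted p of 0.000321 and 0.000459. Fos fell 1.59-fold, Junb 1.23-fold and the Notch ligand gene Jag1 1.24-fold. The calls of Fos, Junb and Jag1 were lost without the untreated or the 20 min array, and that of Junb also without the 200 min array. From 80 to 240 min the slopes of Fos and Junb were positive (0.087 and 0.018 per hour), as they were with the step as a block (0.034 and 0.0010), and up to 60 min those of Krt5, Jun, Myc and Hes1 were opposite in sign to the trend; none of these passed. The Notch target Hes1 fell 1.36-fold (adjusted p = 0.00325), and Notch1 missed the threshold (adjusted p = 0.0546). Of the reference genes, Actb did not pass (adjusted p = 0.57) and Gapdh rose 1.08-fold (adjusted p = 0.0116). Both were read on control probe sets of the array, and the Gapdh one is the 5' probe set of the ratio used for RNA integrity. The Gapdh call was lost when arrays were centred on their medians (adjusted p = 0.0615).

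Gene lists were compared with all other genes along the linear trend, and 12 of 30 passed with camera at the preset correlation. Immediate early genes, which respond to growth factors and stress within minutes, fell together: 22 of 31 fell and 0 rose (camera adjusted p = 4.67e-08; 23 past the threshold adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). Beside Egr2 and Dusp1, Atf3 fell 2.45-fold and Klf6 2.41-fold, while Egr1 had a slope of -0.0028 per hour (adjusted p = 0.974). Genes of epidermal differentiation also fell, 19 of 25 with 0 rising (camera adjusted p = 4.22e-08; 19 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). Scel (sciellin) fell 2.41-fold, Cst6 (cystatin E/M) 2.07-fold, Prdm1 (Blimp1) 2.02-fold and Cdsn (corneodesmosin) 1.79-fold. No list passed with an estimated correlation.

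Cell cycle genes rose. Of the G1/S and DNA replication genes 15 of 20 rose and 0 fell (camera adjusted p = 9.15e-05; 15 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation). Examples were Ccne1 (cyclin E1) at 1.66-fold, the ribonucleotide reductase genes Rrm2 and Rrm1 at 1.61-fold and 1.56-fold, and the replication licensing gene Mcm3 at 1.48-fold. Of the G2/M genes 13 of 22 rose and 0 fell (camera adjusted p = 0.00146; 14 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). The mitotic kinesin gene Kif20a rose 2.0-fold, Ccnb2 (cyclin B2) 1.97-fold, Cdc20 1.45-fold and Cdc25c 1.44-fold.

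**Figure D2:**
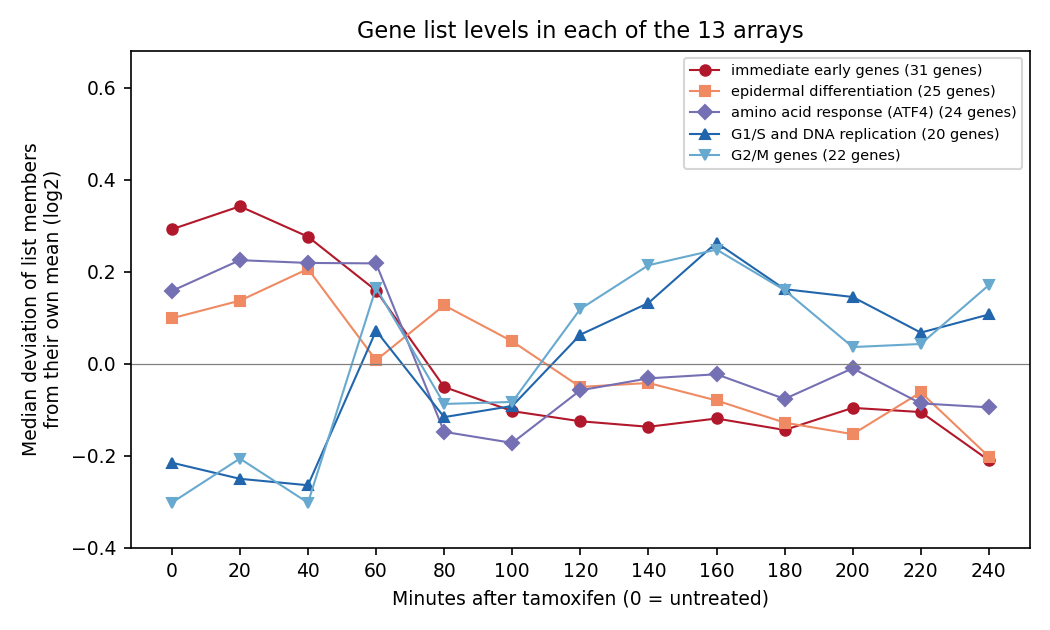
Median, over the members of each list, of the log2 deviation from each gene's mean over the 13 arrays, against minutes after tamoxifen with 0 for untreated cells; each point is 1 array. The amino acid response list goes from 0.22 at 60 min to -0.15 at 80 min, and the G2/M list is at 0.17 at 60 min, -0.087 at 80 min and 0.25 at 160 min.

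Lists of stress, adhesion, metabolism and EGFR signalling also passed with camera at the preset correlation. Of the amino acid response (ATF4) genes 13 of 24 fell and 2 rose (camera adjusted p = 0.000462; 15 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation). With a step between 60 and 80 min as a block the camera direction of this list was up (adjusted p = 0.658). Its members included Ddit3 (CHOP), which fell 2.43-fold, Chac1, which fell 1.75-fold, and Stc2, which fell 1.63-fold. Of the desmosome and tight junction genes 8 of 18 fell and 0 rose (camera adjusted p = 0.000462; 11 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). The desmocollin gene Dsc2 fell 2.40-fold and the claudin genes Cldn4 and Cldn1 fell 1.75-fold and 1.55-fold. Cholesterol synthesis genes fell in 8 of 19 cases and rose in 2 (camera adjusted p = 0.00967; 11 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation), with Idi1 at 1.66-fold and Dhcr7 at 1.54-fold lower. Of the EGFR ligand and MAPK feedback genes 9 of 16 fell and 3 rose (camera adjusted p = 0.0198; 12 adjusted over the list alone; adjusted p = 0.367 with an estimated correlation), with the EGFR ligand genes Epgn and Ereg 2.30-fold and 1.85-fold lower. Oxidative phosphorylation genes rose in 9 of 22 cases with 0 falling (camera adjusted p = 0.0181; 9 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation), by small amounts such as 1.26-fold for Atp5c1.

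Targets of p63 in epidermis went both ways: 6 of 30 rose and 5 fell, and the list did not shift against other genes (camera adjusted p = 0.843; 10 adjusted over the list alone). Ripk4, a kinase needed for epidermal differentiation, rose 1.31-fold, while Cldn1 fell 1.55-fold, the hexokinase gene Hk2 1.47-fold and the transcription factor gene Ovol1 1.34-fold. Of the p53 pathway targets 5 of 22 rose and 4 fell (camera adjusted p = 0.71; 9 adjusted over the list alone). Apaf1 rose 1.64-fold, and Plk3, Gadd45a and Pmaip1 fell 2.55-fold, 2.13-fold and 1.48-fold. Of the basal keratinocyte genes 3 of 17 rose and 4 fell (camera adjusted p = 0.843; 8 adjusted over the list alone). The camera direction of this list was down, against a median slope of 0.0052 and a mean slope of 0.0031 per hour. In it Sox9 fell 1.67-fold, Krt16, a keratin of activated keratinocytes, fell 1.33-fold, and Cav1 rose 1.52-fold.

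Within the 9 arrays from 80 to 240 min, 6 of the 12 lists were still past the camera threshold. The differentiation genes had the smallest camera adjusted p there (5.82e-17), which does not measure the size of the shift. They were followed by G1/S genes (0.0013), unfolded protein response genes (0.00462), cholesterol synthesis genes (0.00556), immediate early genes (0.019) and oxidative phosphorylation genes (0.0204). The amino acid response list was at an adjusted p of 0.894 in those arrays and the G2/M list at 0.107. With the step between 60 and 80 min as a block, 6 lists passed. Those of G2/M genes (camera adjusted p = 0.0732), EGFR and MAPK feedback (0.238), desmosome and tight junction (0.1) and matrix proteases (0.0732) lost their calls. So did the amino acid response and ribosome biogenesis lists. These values rest on the preset correlation.

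Markers of other cell types were followed over time, and whether such cells were in the cultures was not tested. The filter on dim genes left 7 of 19 fibroblast, 2 of 15 immune cell and 3 of 12 endothelial and muscle markers, and 7 of 9 melanocyte markers. The melanocyte genes Dct, Tyrp1 and Pmel were abundant, at percentiles 93.1, 88.4 and 88 of mean level among all genes. Their slopes had adjusted p of 0.882, 0.991 and 0.755. Mitf fell 1.27-fold (adjusted p = 0.00699). Of 7 tested fibroblast markers 3 rose and 0 fell (camera adjusted p = 0.141; 3 adjusted over the list alone): S100a4 1.49-fold, Vim 1.26-fold and Fbln1 1.17-fold, none of them restricted to fibroblasts. The collagen gene Col1a1 did not pass (adjusted p = 0.262). Acta2, a smooth muscle actin gene, rose by 0.22 on the log2 scale over 4 h (adjusted p = 0.0165). Of the immune cell markers tested, Cd68 fell by 0.55 on the log2 scale over 4 h (adjusted p = 0.000979), and Csf1r did not pass (adjusted p = 0.784). The untested members of that list were dim, from percentile 1.2 (Ptprc) to 38.4 (H2-Ab1), so the fall of Cd68 is not shown to come from immune cells.

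The late window was set against the early window to leave the untreated array out. At 180 to 240 min Cxcl5 was at 9.21 ± 0.224 against 8.13 ± 0.718 at 20 to 80 min (SD over 4 arrays each; difference 1.07, adjusted p = 0.0113). Ddit4l was higher by 0.97, Tnfrsf18 by 0.92, Sostdc1 by 0.88 and Dcxr by 0.84. Dusp10 fell by 1.41, Ptgs2 by 1.38, Egr2 by 1.38, Edn1 by 1.21 and Dusp1 by 1.19 on the log2 scale (adjusted p = 0.00354 for Dusp10, Ptgs2, Edn1 and Dusp1). The contrast called 1953 genes, 1127 higher and 826 lower late, and 1907 of them also had a linear trend, in the same direction. Both fits use the same arrays, so this overlap is no independent support. The balance of directions in the contrast reversed with median centring (811 higher, 1035 lower) and without the 200 and 220 min arrays (634 genes, 268 higher and 366 lower). The contrast called 986 genes without the 20 min array, 1054 without the 40 min array and 1192 without the 220 min array. The count rose to 2707 without the 80 min array and to 3552 with array weights. A fit with the 80 min array as the only one of the early window left 1 array on that side, so its count cannot show what the contrast rests on.

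In this contrast 11 lists passed with camera and 0 with an estimated correlation. Differentiation genes were lower late in 16 of 25 cases with 0 higher (camera adjusted p = 6.86e-10; 18 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). Immediate early genes were lower in 20 of 31 cases and higher in 2 (camera adjusted p = 6.93e-07; 23 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). G1/S genes were higher in 6 of 20 cases with 0 lower (camera adjusted p = 0.000909; 7 adjusted over the list alone; adjusted p = 0.492 with an estimated correlation). Without the 40 min array 7 lists passed.

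The spline asked for changes that a straight line misses. Among genes past this test alone whose fitted curve bends above the line joining its ends, Sgk1, a serum- and glucocorticoid-induced kinase gene, and Slc16a3, a lactate transporter gene, had the largest fitted ranges, 0.57 and 0.56 on the log2 scale (adjusted p = 0.0398 and 0.00491). Deptor (0.51), Hnrnpa2b1 (0.37) and Slc38a4 (0.30) followed. Among those bending below it the largest ranges were those of Artn, a neurotrophic factor gene, with 0.80 (adjusted p = 0.013), and of the chemokine gene Ccl20 with 0.57 (adjusted p = 0.0157), then Dsc3, Tmem185b and Znrf1. A bend need not be a turn: Sgk1 was at 11.89 ± 0.144 in the 4 arrays from 100 to 160 min and 11.86 ± 0.0525 at 180 to 240 min (SD). The spline called 1850 genes, of which 1811 also had a linear trend and 39 did not, 8 bending above the line and 31 below it. In the arrays from 80 to 240 min alone it called 0.

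The early window against the untreated array was the only comparison with cells not given tamoxifen, and it called 0 of 7436 genes with limma. At an unadjusted level 112 genes were under 0.05, 33 higher and 79 lower after tamoxifen. The immediate early gene Egr1 read 9.65 in untreated cells and 8.74 ± 0.116 at 20 to 80 min (SD over 4 arrays), and its adjusted p, 0.657, was the smallest of all. Fos read 9.19 untreated and 8.62 ± 0.332 early, and Kif20a read 8.44 untreated and 8.84 ± 0.304 early. As lists, immediate early genes were lower after tamoxifen in 29 of 31 cases by estimate, with 0 past the threshold (camera adjusted p = 4.27e-10; 1 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). G2/M genes were higher in 20 of 22 cases by estimate, with 0 past the threshold (camera adjusted p = 0.000187; 0 adjusted over the list alone; adjusted p = 0.534 with an estimated correlation). Of the 12 lists past camera here, 0 passed with an estimated correlation and 0 with fry, and all rest on 1 untreated array.

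RNA quality and hybridisation controls were followed over the 13 arrays. None of 6 control measures correlated with time after adjustment, and the closest were the hybridisation spikes (Pearson r = 0.501, permutation p = 0.0826, adjusted 0.248; Spearman rho = 0.481, permutation p = 0.0976, adjusted 0.293; r = 0.481 without the 2 arrays farthest in time from the median) and 18S rRNA (r = -0.5, permutation p = 0.0696, adjusted 0.248; rho = -0.549, permutation p = 0.0542, adjusted 0.293; r = -0.493 without those 2). An 18S probe set read 958.6 intensity units at 60 min and between 346.3 and 552 in the other arrays. The log2 ratio of 3' to 5' Gapdh probe sets lay between -0.153 and -0.0935 in all arrays. The 2 leading principal components held 51.5% and 21.3% of the variance. Scores on the leading one went from -7.86 at 60 min to 0.32 at 80 min, and on the next the arrays at 200 and 220 min stood at 11 and 9.57 with 180 and 240 min at -5.11 and -6.51.

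**Figure D3:**
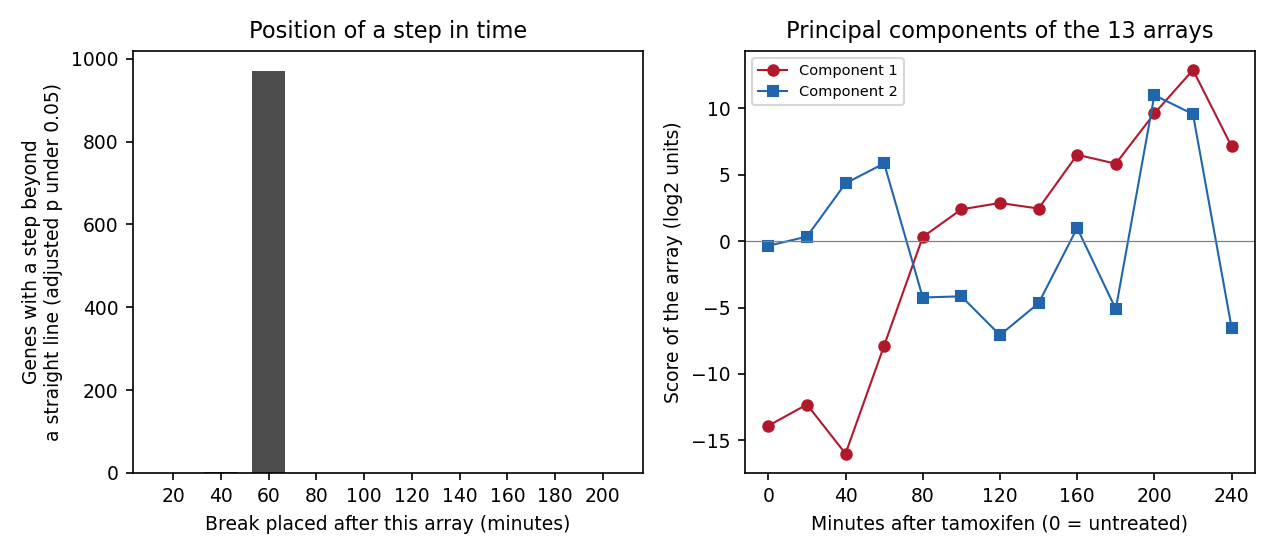
Left, number of genes with a step beyond a straight line (adjusted p under 0.05) for a break after each array from 20 to 200 min; right, scores of the 13 arrays on the 2 leading principal components (log2 units) against minutes after tamoxifen. The break after 60 min gives 971 genes and the others 1 or 0, and component 2 sets 200 and 220 min apart from 180 and 240 min.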

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

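The step between 60 and 80 min was noticed in the principal components, and its tests were chosen after that result was seen. The test on second probe sets also uses this break, although its prediction was recorded as written beforehand. The counts over other orders of the arrays were planned beforehand and do not test the step.

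The counts over time were larger than other orders of the same arrays gave. The real order gave 2968 genes with a linear trend, and 1 of 100 orders, the real one itself, gave as many; the highest of the others gave 1687. For the spline it was again 1 of 100, with 1850 genes against 1449 at most. For late against early it was 1 of the 35 splits of the 8 arrays, with 1953 genes against 920 at most, from the split that sets 20, 40, 60 and 200 min against 80, 180, 220 and 240 min. Chance order of the arrays is unlikely as the source of these counts, though 1 of 100 and 1 of 35 are the smallest shares these tests could give. The counts say nothing about whether induction, handling or a batch made the order matter.

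The level of 971 genes stepped between the 60 and 80 min arrays beyond any straight line, which argues against straight-line drift with no step, since a break at each other position gave 1 gene or 0. A gradual change in most of the genes is not excluded: 50.1% of the 1850 genes past the spline test were fitted more closely by the step than by a line. A difference in hybridisation or scanning that acts probe by probe is argued against by 670 genes with a second probe set, of which 94.6% stepped the same way on both. A difference in RNA integrity cannot be told apart, since 0 of 3 control genes shifted in 3' to 5' ratio and a miss does not show equal quality. A batch of dishes, labelling or collection shared by the arrays up to 60 min also stays open: the hybridisation spikes were higher from 80 min by 0.363 on the log2 scale (exact permutation p = 0.0196, adjusted 0.118), with 3 of 36 pairs the other way, and a delayed response to induction, which would give such a step too, was not tested against it.

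Within windows of 4 arrays, 5 of 108 groups of values held an array far from the other 3, about the number that chance gives at 1 in 20. The median of the amino acid response list was -0.148 at 80 min and between 0.218 and 0.225 at 20 to 60 min. The 18S rRNA level was 9.109 at 100 min and between 8.83 and 8.849 at 120 to 160 min. The heat shock list was at 0.0305 at 120 min and between -0.0158 and -0.0095 in the rest of its window. At 200 min the hybridisation spikes read 10.04, against 10.24 to 10.26 in the rest of the late window, and the reference housekeeping list was at 0.0543, against 0.017 to 0.0208.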

How the results depend on the processing

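Fits on part of the course, with a step block, or without the 200 and 220 min arrays were chosen after seeing the data; where no cause is named, the cause was not tested. With each probe set named to 1 gene and above the 40th percentile of mean level tested separately, 4463 probe sets, not genes, had a linear trend (more tests). Genes with a linear trend numbered 697 with a change of at least 0.5 (a stricter rule), 5 in the 9 arrays from 80 to 240 min, 0 in the 4 arrays up to 60 min (fewer arrays) and 1 with a step between 60 and 80 min as a block. Without each array in turn they numbered 2323 to 3087, spline genes 1244 to 2458, and genes of late against early 986 (without 20 min) to 2707. The spline called 0 genes from 80 to 240 min. Late against early called 3552 with array weights, 634 without 200 and 220 min (268 higher, 366 lower) and 1846 with median centring (811 higher, 1035 lower). With only 80 min of the early window 1 array was left on that side, so no count is given. Early against untreated called 1 gene, Mmp13, without the filter on dim genes. In the linear trend 0 lists passed with an estimated correlation, 21 with directional fry, 29 with mixed fry, 6 from 80 to 240 min and 6 with the block. In late against early, 0 passed with an estimated correlation, 29 with mixed fry and 7 (without 40 min) to 13 without 1 array. In early against untreated, 0 passed with an estimated correlation, 0 with directional fry and 0 with mixed fry. The Trp63 slope lost its call without the dim filter, both over genes (0.065) and over all 20393 probe sets named to 1 gene (adjusted p = 0.0606). It also lost the call with median centring (0.064), with the mean of its probe sets (0.055) and without the untreated array (0.065). The slope ranged from 0.051 to 0.082 without each array. It reversed from 80 to 240 min (-0.035), up to 60 min (-0.013) and with the block (-0.033). Slopes also reversed from 80 to 240 min for Cxcl5 (-0.022), Fos (0.087) and Junb (0.018), and with the block for Cxcl5 (-0.023), Fos (0.034) and Junb (0.0010). Up to 60 min they reversed for Cxcl5 (-0.039), Ddit4l (-0.11), Tnfrsf18 (-0.16), Sostdc1 (-0.25), Dcxr (-0.089), Ces2g (-0.20), Ak1 (-0.21), Sncg (-0.14), Edn1 (0.049), Cidea (0.023), Krt5 (-0.045), Jun (0.023), Myc (0.094) and Hes1 (0.022). With the block the camera direction reversed for the amino acid response (adjusted p = 0.658) and ribosome biogenesis (0.909) lists. Low signal limits the dim genes, which were left out.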

Other observations

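Other fixed lists gave further named changes along the linear trend. Hmox1 (heme oxygenase 1) fell 2.62-fold and Cyp1b1 2.09-fold, and of the NRF2 and AhR response genes 2 of 14 rose and 4 fell (camera adjusted p = 0.946; 7 adjusted over the list alone). Among TGF-beta and BMP response genes 4 of 16 rose and 6 fell (camera adjusted p = 0.44; 12 adjusted over the list alone). Inhba (activin A) fell 2.76-fold and Ccn2 fell 2.02-fold, and the median slope of this list, 0.00063 per hour, was opposite in sign to its mean of -0.047 and to camera. Of the NF-kB and inflammatory genes 2 of 14 rose and 5 fell (camera adjusted p = 0.165; 7 adjusted over the list alone), with Il1a 2.35-fold lower and Icam1 1.78-fold higher. Hypoxia and glycolysis genes rose in 9 of 15 cases and fell in 4 (camera adjusted p = 0.333; 14 adjusted over the list alone), with Pfkl 2.0-fold and Pdk1 1.92-fold higher beside Adm and Ndrg1 (1.65-fold lower). Of the Wnt and hedgehog response genes 5 of 11 rose and 1 fell (camera adjusted p = 0.116; 6 adjusted over the list alone), among them Wnt10a at 1.77-fold, Wnt4 at 1.63-fold and Ccnd1 (cyclin D1) at 1.28-fold higher. The Notch pathway list had 1 of 10 up and 4 down (camera adjusted p = 0.453; 7 adjusted over the list alone), with the ligand gene Dll1 1.75-fold higher.

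Of the circadian clock genes 6 of 11 fell and 2 rose (camera adjusted p = 0.0727; 8 adjusted over the list alone), with Bhlhe40 2.04-fold and Clock 1.82-fold lower. Glucocorticoid response genes fell in 4 of 11 cases and rose in 2 (camera adjusted p = 0.165; 6 adjusted over the list alone), with Zfp36 2.12-fold and Klf9 1.87-fold lower. Unfolded protein response genes fell in 6 of 19 cases with 0 rising (camera adjusted p = 0.0451; 6 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation), with Dnajb9 1.66-fold and Hspa5 (BiP) 1.46-fold lower. Of the heat shock genes 3 of 14 rose and 5 fell (camera adjusted p = 0.175; 8 adjusted over the list alone), with Cryab 1.81-fold lower and Hspa1a 1.34-fold higher. Matrix protease and motility genes fell in 7 of 16 cases and rose in 1 (camera adjusted p = 0.0198; 9 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation), with Adamts1 2.06-fold and Plaur 2.01-fold lower. Ribosome biogenesis genes fell in 6 of 21 cases with 0 rising (camera adjusted p = 0.0198; 6 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation), led by Nop58 at 1.76-fold lower. With a step between 60 and 80 min as a block the camera direction of this list was up (adjusted p = 0.909). Of 17 ribosomal protein genes 2 rose (camera adjusted p = 0.175; 1 adjusted over the list alone), and of 12 reference housekeeping genes 4 rose and 1 fell (camera adjusted p = 0.118; 5 adjusted over the list alone). Estrogen response genes fell in 5 of 8 cases and rose in 1 (camera adjusted p = 0.0634; 6 adjusted over the list alone), and BCL2 family and apoptosis genes fell in 5 of 16 cases and rose in 1 (camera adjusted p = 0.238; 6 adjusted over the list alone). Of 7 melanocyte markers 1 fell (camera adjusted p = 0.467; 1 adjusted over the list alone). Interferon-stimulated genes, immune cell markers, and endothelial and muscle markers had 4, 2 and 3 tested genes and were not tested as lists.

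The high level of immediate early genes in the untreated array was weighed with tests chosen after it was seen. Their median there was 0.141 above the mean of the next 4 arrays, with 29 of 31 genes higher, but the arrays at 20, 40 and 60 min stood 0.199, 0.311 and 0.242 above the 4 arrays after them. Whether the untreated array stands apart over all genes cannot be told from its residual spread about the straight line. That spread, corrected for the array's place at the end of the course, ranked 1 of 13 from the lowest (0.0745, against 0.137 at 60 min). A line fitted to levels that step early in the course runs closer to the first array than to those beside the step. The low rank may therefore reflect misfit of the line. On the leading principal component the untreated array scored -13.9, between the arrays at 20 min (-12.3) and 40 min (-16). On the next it scored -0.343, against 0.346 and 4.36. On these components it thus lay near those arrays, which does not cover the remaining variance. Handling or medium at collection, rather than the fusion protein, may be the source of the high immediate early level. This cannot be told apart, because 0 of the arrays analysed here came from cells without the fusion protein or from a course without tamoxifen.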
